A study of Mus musculus with 12 samples.

How the data were processed

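RNA was measured in 12 libraries of sorted mouse bone marrow cells, 3 for each of 4 gates, with groups and replicate numbers taken from the labels. Per the labels' protocols, RNA was extracted with a column micro kit, amplified with a SMARTer ultra-low-input kit and made into libraries with Nextera XT. Such low-input amplification gives genes with few transcripts many zeros. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.39, STAR 2.7.10b, RSEM 1.3.2, limma, edgeR 3.36.0 and the build mm39, without saying what each was used for. The deposited count table holds expected counts per Ensembl gene, as the authors made them, with totals of 16937905 to 26758916 per library. Of the values above 0, 77.8% equalled a whole number exactly, with no tolerance. The annotation release is not given in the sources used here.

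A second deposited table holds a signal per gene and library for 15442 genes. In every library its rank order equals that of the expected counts (Spearman correlation 1), and 90.3% of its sorted values lie within 1% of the mean of the sorted expected counts, so it was read as quantile-normalized counts. The same table holds the authors' deposited log2 fold changes and p-values for Il7rLTpos_a4b7hi against Il7rLTneg_a4b7hi. The quantile-normalized signal was not used for a test, because it forces the same distribution on every library.

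Expected counts were rounded to whole numbers. Of 56980 genes, 36392 had no count in any library, and edgeR's filterByExpr kept 13672. Symbols came from the deposited table for 13473 tested genes and from a gene name table for 179, and 20 kept their identifier. The reference at hand is of another build than mm39, so no coordinates are given. Counts of genes that share reads with close relatives, such as Hba-a1 and Hba-a2 or the Ms4a family, depend on how those reads were divided. Nothing in the sources used here states counting by strand, so reads of overlapping antisense genes may be mixed.

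The main test was edgeR 4.0.16 under R 4.3.3, with TMM factors, robust glmQLFit over all 4 groups and glmQLFTest, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. Gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 68 tests of 17 lists with at least 4 measured genes in 4 comparisons. These lists cover ILC transcription factors, ILC precursor surface and signalling, early lymphoid, B lineage, T lineage, NK lineage, myeloid, dendritic cell, stem cell and multipotent progenitor, erythroid and megakaryocyte, mast cell and basophil, cell division, DNA replication, Notch target, E protein and Id, interferon response and immediate early genes. Sort gate, eosinophil and sex-linked genes were described without a list test. None of the 17 camera calls held with an estimated inter-gene correlation, which gave the highest adjusted p of the alternatives in each; the lowest ranged from 1e-09 to 0.016 over these calls.

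Genes were named by a rule fixed before the data were examined, with fewer named than it selects, in order of rank. It takes the sort gate genes and ILC transcription factors, the 8 largest changes in each direction among called genes with an absolute log2 fold change of at least 1, at least 10 CPM in the higher group and no overlap between groups, and up to 4 called members of each list with the smallest p. It adds up to 2 further members of a list that camera called. Some genes the rule selects are not reported here. Predicted genes, antigen receptor segments, sex-linked and mitochondrial genes were left out of the 8 largest. A fold against a group at 0 was computed against a floor of 3 counts per library, and a ratio to 1 to 3 counts has an exact Poisson interval at 95%. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

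The procedure was tested on simulated data, with negative binomial counts from the real means, dispersions and library sizes and 200 genes changed. For the α4β7 step, on 12999 genes, 23.9% of genes changed 2-fold, 46.3% changed 4-fold and 87.9% changed 8-fold were called, with 4 false calls. For the comparison by Il7r history, on 13026 genes, the shares were 10.4%, 68.7% and 86.4%, with 3 false calls. For the Tcf7 step, on 13044 genes, they were 17.9%, 73.1% and 78.8%, with 3 false calls, and for the comparison across both steps, on 13009 genes, 22.4%, 70.1% and 81.8%, with 7 false calls.

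Alternatives were size factors by RLE, no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Leaving out all libraries numbered 3 was added after seeing the data. Adjusted p-values that DESeq2 gives as NA stayed out of its counts. Figures were drawn with matplotlib from the tables of results.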

Results

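The series profiled polyadenylated RNA of sorted mouse bone marrow progenitors, to compare early intermediates on the way to innate lymphoid cells (ILCs), lymphocytes without rearranged antigen receptors, isolated by different sorting strategies. The C57BL/6 mice carried an Il7r-iCre driver with a Cre-activated YFP reporter, so that YFP marks cells with a history of Il7r expression, and a GFP reporter at Tcf7, which encodes the transcription factor TCF-1. All 4 gates were lineage-negative, Thy1.2-negative, Kit-positive, 2B4-positive and Flt3-high. Il7rLTpos_a4b7lo was YFP-positive, GFP-negative and low for the integrin α4β7, Il7rLTpos_a4b7hi was YFP-positive, GFP-negative and α4β7-high, Il7rLTpos_Tcf7pos was YFP-positive, GFP-positive and α4β7-high, and Il7rLTneg_a4b7hi was YFP-negative, GFP-negative and α4β7-high. Each gate had 3 libraries, 12 in all, of the same labelled batch. Total expected counts ranged from 16937905 to 26758916 per library, and 13672 genes were tested. Values are mean CPM, counts scaled to the same library size, ± SD with n = 3 libraries. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Counts of DESeq2 calls are given beside some edgeR counts and may include false calls. With the 6 libraries compared by Il7r history split in the 9 other ways, DESeq2 still called 51 to 87 genes. The labels do not say whether libraries of a gate came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Sex-linked transcripts, given below, differed between libraries of the same gate, so this spread may also hold differences between animals.

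From the α4β7-low to the α4β7-high YFP-positive gate, transcripts of several ILC transcription factors rose and the lymphoid gene Dntt fell. Nfil3 (ENSMUSG00000056749), a transcription factor needed for ILC development, rose from 36.6 ± 8.80 to 689 ± 136 CPM, a log2 fold change of 4.23 (SE 0.20, adjusted p = 1.4e-06). Dntt (ENSMUSG00000025014), the template-independent DNA polymerase of antigen receptor joining, fell from 6050 ± 478 to 634 ± 216 CPM (log2 fold change -3.25, SE 0.34, adjusted p = 0.00065). In all, 237 genes changed, 186 higher and 51 lower in Il7rLTpos_a4b7hi. Of these, 236 had no overlap between the libraries of the gates, which a call nearly guarantees, so this is no separate evidence. Of all tested genes 19.2% had no overlap, against the 10% that chance gives.

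Itgb7 (ENSMUSG00000001281), the β7 chain used for sorting, rose from 35.6 ± 4.12 to 881 ± 262 CPM (adjusted p = 3.6e-06), and Itga4, the α4 chain, rose from 86.3 ± 21.0 to 402 ± 162 CPM (adjusted p = 0.0011). Tcf7 (ENSMUSG00000000782) rose from 0.570 ± 0.842 to 75.5 ± 73.6 CPM (adjusted p = 0.0052) although both gates were GFP-negative, and its 3 Il7rLTpos_a4b7hi libraries held 42.8, 160 and 24.0 CPM. Il7r was at 126 ± 9.68 CPM in the α4β7-low and 19.6 ± 18.4 CPM in the α4β7-high gate and was not called (adjusted p = 0.45). Kit, Flt3 and Cd244a, which encodes 2B4, were not called either, so that 3 of the 7 measured sort gate genes rose, as also adjusted over the list alone.

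Of 14 measured ILC transcription factors, 4 rose, 1 fell and 9 were not called, and 7 rose and 1 fell adjusted over the list alone. Id2, an inhibitor of E proteins, rose from 10.4 ± 3.27 to 150 ± 63.0 CPM (adjusted p = 0.0021). Tox rose from 23.8 ± 9.07 to 135 ± 46.3 CPM (adjusted p = 0.0035) and Gata3 from 5.47 ± 1.68 to 37.3 ± 26.8 CPM (adjusted p = 0.041). Ets1 fell from 164 ± 13.3 to 23.8 ± 15.4 CPM (adjusted p = 0.013). Zbtb16, which encodes PLZF, had no count in the α4β7-low libraries and 4.50 ± 3.57 CPM in the α4β7-high ones (adjusted p = 0.15). The list was higher by camera, limma's competitive gene set test (adjusted p = 6.49e-06), but the call was lost with an estimated correlation (adjusted p = 0.158). Among 13 genes of ILC precursor surface and signalling, 1 rose, Cd7, from 2.48 ± 2.08 to 44.5 ± 10.95 CPM (adjusted p = 0.0096), and 6 rose adjusted over the list alone. Its camera adjusted p of 0.0126 became an adjusted p of 0.158 with an estimated correlation, and an adjusted p of 0.069 without Il7rLTpos_a4b7lo replicate 1. No NK lineage gene of 9 was called over all genes by edgeR, with 3 at an unadjusted p under 0.05 and 3 called by DESeq2, and 1 rose adjusted over the list alone. Il2rb, a chain of the IL-2 and IL-15 receptors, was at 6.67 ± 7.67 and 63.4 ± 41.8 CPM. The list was higher by camera (adjusted p = 0.03), with an adjusted p of 0.158 with an estimated correlation and an adjusted p of 0.095 without Il7rLTpos_a4b7lo replicate 1. In the 6 edgeR fits that each left out 1 library of these gates, Gata3 was called only without Il7rLTpos_a4b7hi replicate 3 (adjusted p = 0.066 to 0.16 in the others). Ets1 was not called without Il7rLTpos_a4b7lo replicate 1 or Il7rLTpos_a4b7hi replicate 1 (adjusted p = 0.053 and 0.069), nor Cd7 without Il7rLTpos_a4b7lo replicate 2 (adjusted p = 0.056).

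**Figure D1:**
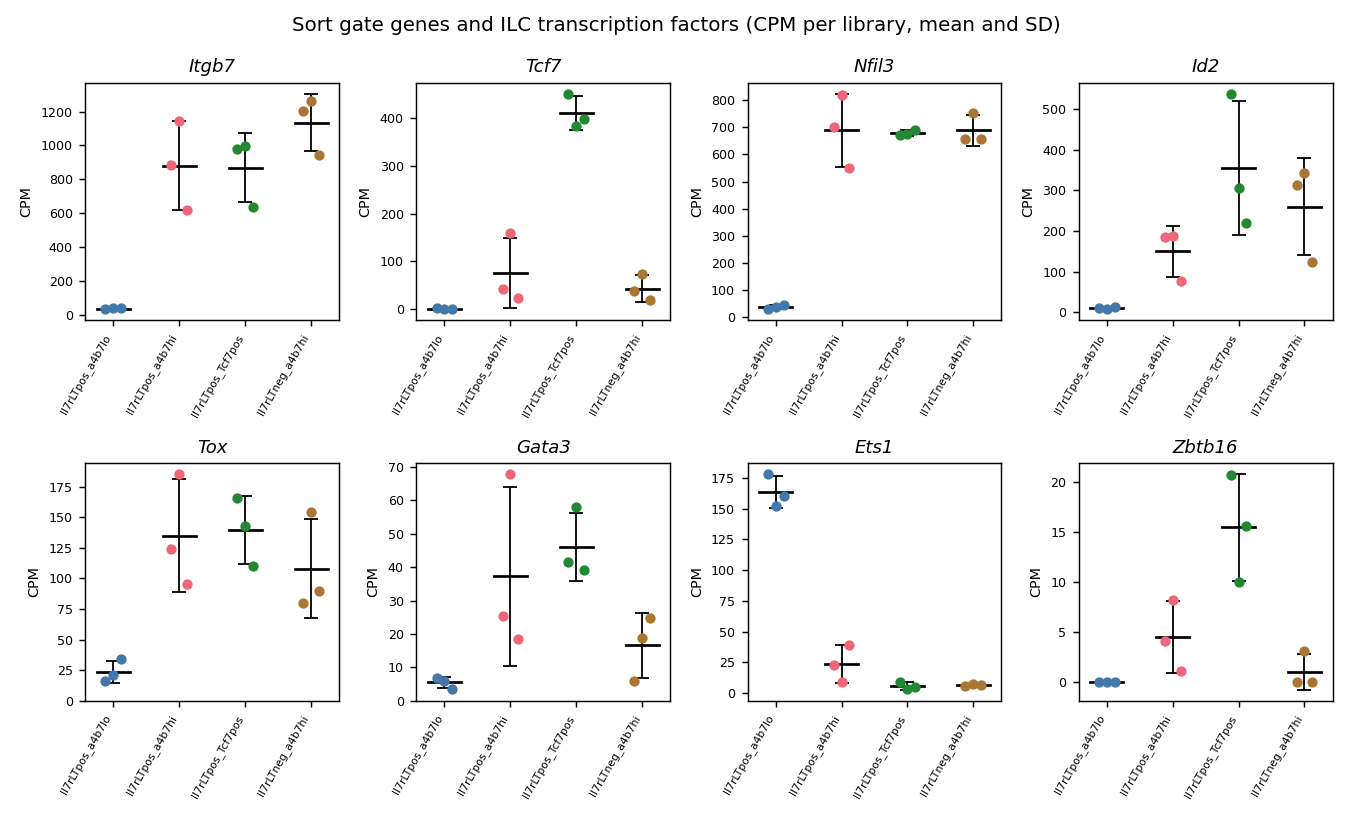
Expression in CPM (linear vertical axis) of sort gate genes and ILC transcription factors in the 4 gates, with a point per library, the mean as a line and the SD as an error bar (n = 3). Nfil3 averaged 36.6 CPM in Il7rLTpos_a4b7lo and 689 CPM in Il7rLTpos_a4b7hi.

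Early lymphoid genes moved both ways in the α4β7 step. Of 11 measured, 2 fell, 2 rose and 7 were not called, and 6 fell and 2 rose adjusted over the list alone. Cd27 fell from 268 ± 24.0 to 138 ± 15.2 CPM (adjusted p = 0.0029). Ccr7, a homing receptor, rose from 43.4 ± 14.3 to 102 ± 5.55 CPM (adjusted p = 0.016). The list was lower by camera (adjusted p = 0.00974), with an adjusted p of 0.33 with an estimated correlation, and adjusted p-values of 0.057 and 0.059 without replicates 1 and 3 of Il7rLTpos_a4b7lo. Of 12 B lineage genes 1 fell, Ighm, the immunoglobulin mu heavy chain gene, from 1638 ± 187 to 932 ± 186 CPM (adjusted p = 0.019). Of 14 T lineage genes 1 fell, Lat, a T cell signalling adaptor, from 29.7 ± 5.30 to 6.87 ± 2.91 CPM (adjusted p = 0.043). Adjusted over the list alone, 1 B lineage gene fell, and 1 T lineage gene fell and 1 rose. With 1 library left out, Ccr7 was not called without Il7rLTpos_a4b7lo replicate 1 or Il7rLTpos_a4b7hi replicates 1 or 3 (adjusted p = 0.059 to 0.061). Ighm was not called without Il7rLTpos_a4b7lo replicates 1 or 3 or Il7rLTpos_a4b7hi replicates 1 or 2 (adjusted p = 0.056 to 0.09), and Lat was called only without Il7rLTpos_a4b7hi replicate 1 (adjusted p = 0.075 to 0.17 in the others).

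Of 17 myeloid and granulocyte-monocyte genes, 3 rose and 14 were not called, and 11 rose adjusted over the list alone. Irf8, a transcription factor of monocyte and dendritic cell development, rose from 653 ± 9.38 to 1999 ± 151 CPM (adjusted p = 9.6e-05). Ms4a6c rose from 23.1 ± 13.4 to 203 ± 77.6 CPM (adjusted p = 0.0021) and Ly86 from 124 ± 16.6 to 261 ± 22.8 CPM (adjusted p = 0.0042). The list was higher by camera (adjusted p = 4.23e-07), with an adjusted p of 0.223 with an estimated correlation. Mpo and Elane, granule protein genes of the same list, were at 11277 and 2514 CPM in replicate 3 of Il7rLTpos_a4b7hi, against 2165 and 1882 CPM of Mpo and 48.5 and 4.43 CPM of Elane in replicates 1 and 2. Of 9 mast cell and basophil genes and 12 erythroid and megakaryocyte genes 0 were called by edgeR, with 4 and 1 at an unadjusted p under 0.05 and 1 and 0 called by DESeq2; 1 and 0 rose adjusted over the list alone. Both lists were higher by camera (adjusted p = 0.0128 and 0.03), with adjusted p = 0.532 and adjusted p = 0.748 with an estimated correlation. The first had adjusted p = 0.25 without Il7rLTpos_a4b7hi replicate 3 and 0.12 without Il7rLTpos_a4b7lo replicate 1, in a range of 0.00019 to 0.53 over its alternatives. The second had adjusted p = 0.57 without Il7rLTpos_a4b7hi replicate 3 and 0.2 without Il7rLTpos_a4b7lo replicate 2, in a range of 0.00023 to 0.75.

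The other genes with the largest changes in the α4β7 step included Fgr, a Src family kinase, from 2.47 ± 1.45 to 67.5 ± 8.79 CPM (adjusted p = 0.0013), and Ms4a4c, from 3.08 ± 2.26 to 70.0 ± 10.4 CPM (adjusted p = 0.0018). Rab30 was at 0 in the α4β7-low libraries and at least 90.8-fold higher in the α4β7-high ones, taking 3 counts per library as the floor (adjusted p = 0.0032). Mcf2l, with a single count in the α4β7-low gate, had a ratio of 1360 with a 95% counting interval of 244 to 53600 (adjusted p = 0.00095). Ifi205, also with a single count there, had a ratio of 999 with an interval of 179 to 39400 (adjusted p = 0.0021). Pid1 rose from 0.0856 ± 0.148 to 15.1 ± 7.21 CPM (adjusted p = 0.013). Downward, Egfl7 fell from 345 ± 8.28 to 52.8 ± 18.1 CPM (adjusted p = 0.00081) and Ptger2 from 95.5 ± 6.00 to 13.6 ± 8.06 CPM (adjusted p = 0.013). Azin2 fell from 36.3 ± 2.97 to 6.16 ± 1.24 CPM (adjusted p = 0.015) and Afap1l1 from 118 ± 23.7 to 20.3 ± 8.95 CPM (adjusted p = 0.0075). The count of changed genes was 152 and 136 without replicates 1 and 2 of Il7rLTpos_a4b7lo, 153 without replicate 1 of Il7rLTpos_a4b7hi, and 149 in a fit of only these gates. It was 679 with DESeq2, and 74 with the libraries numbered 3 left out, a choice made after seeing the data. Ptger2 was not called without Il7rLTpos_a4b7hi replicate 3 (adjusted p = 0.054), and Azin2 was called only without Il7rLTpos_a4b7hi replicate 1 (adjusted p = 0.06 to 0.08 in the others).

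Between the α4β7-high gates, the Tcf7 GFP-positive one had lower levels of 14 genes and no gene called higher by edgeR. Of 13672 tested genes, 1349 had an unadjusted p under 0.05, 535 higher and 814 lower. Unchanged genes pass this cut at a share of 0.05 by chance. DESeq2 called 86 genes higher, and limma voom 1. Cnn3 (ENSMUSG00000053931), an actin-binding protein gene on the early lymphoid list, fell from 593 ± 9.52 to 242 ± 53.6 CPM in Il7rLTpos_Tcf7pos (log2 fold change -1.29, SE 0.14, adjusted p = 0.0046). Cmah, an enzyme of sialic acid synthesis, fell from 36.1 ± 21.0 to 0.0708 ± 0.123 CPM (adjusted p = 0.0025). Blk, a Src family kinase of B cells, was at 10.5 ± 4.42 CPM in Il7rLTpos_a4b7hi and at 0 in the GFP-positive libraries, at least 71.3-fold lower (adjusted p = 0.036). The 14 genes had no overlap between the libraries of the gates, which a call nearly guarantees, so this is no separate evidence. Of all tested genes 15% had no overlap, against the 10% of chance.

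The further genes that fell in the Tcf7 step included Ralgapa2, from 13.8 ± 7.27 to 0.572 ± 0.140 CPM (adjusted p = 0.04), and Gcnt2, from 110 ± 8.77 to 25.5 ± 3.48 CPM (adjusted p = 0.0046). Tmem119 fell from 153 ± 6.44 to 52.8 ± 13.2 CPM (adjusted p = 0.0056). Pik3ap1, an adaptor of PI3 kinase in B cells, fell from 156 ± 24.0 to 45.9 ± 9.25 CPM (adjusted p = 0.0056), and Lgmn, a lysosomal protease, from 69.8 ± 19.5 to 15.5 ± 2.30 CPM (adjusted p = 0.0056). Tcf7, whose reporter defined the gate, was at 411 ± 35.3 CPM in Il7rLTpos_Tcf7pos and 75.5 ± 73.6 CPM in Il7rLTpos_a4b7hi and was not called (adjusted p = 0.37). No ILC transcription factor of 14 was called over all genes by edgeR, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2, and 1, Ets1, fell adjusted over the list alone. In the GFP-positive and GFP-negative gates Nfil3 was at 678 ± 10.3 and 689 ± 136 CPM, Tox at 140 ± 27.9 and 135 ± 46.3 CPM, Id2 at 354 ± 165 and 150 ± 63.0 CPM. Tox2 was at 16.8 ± 7.98 and 0.396 ± 0.687 CPM. Flt3 was at 366 ± 119 and 847 ± 136 CPM (adjusted p = 0.056), and of the 7 sort gate genes 1 rose and 1 fell adjusted over the list alone.

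Early lymphoid and B lineage genes were lower as lists in the Tcf7 step by camera at its preset correlation, but not with an estimated one. Of 11 early lymphoid genes 1 fell, Cnn3, and 5 fell adjusted over the list alone, with a camera adjusted p of 4.15e-06 and an adjusted p of 0.158 with an estimated correlation. Of 12 B lineage genes 1 fell, Blk, and 3 fell adjusted over the list alone, with a camera adjusted p of 0.000381 and an adjusted p of 0.158 with an estimated correlation. Of the members not called, Dntt was at 251 ± 98.0 CPM in the GFP-positive and 634 ± 216 CPM in the GFP-negative gate, and Ighm at 574 ± 64.7 and 932 ± 186 CPM. The count of 14 was 0 in a fit of only these gates and 0 with the libraries numbered 3 left out, 313 with DESeq2 and 8 with limma voom. It was 8 without replicate 1 and 8 without replicate 2 of Il7rLTpos_a4b7hi, and 26 without replicate 2 and 26 without replicate 3 of Il7rLTpos_Tcf7pos (the other fits with 1 library left out gave 10 and 11). Blk was called in none of these 6 fits (adjusted p = 0.052 to 0.12), and Ralgapa2 only without Il7rLTpos_a4b7hi replicate 3 (adjusted p = 0.079 to 0.17 in the others).

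**Figure D2:**
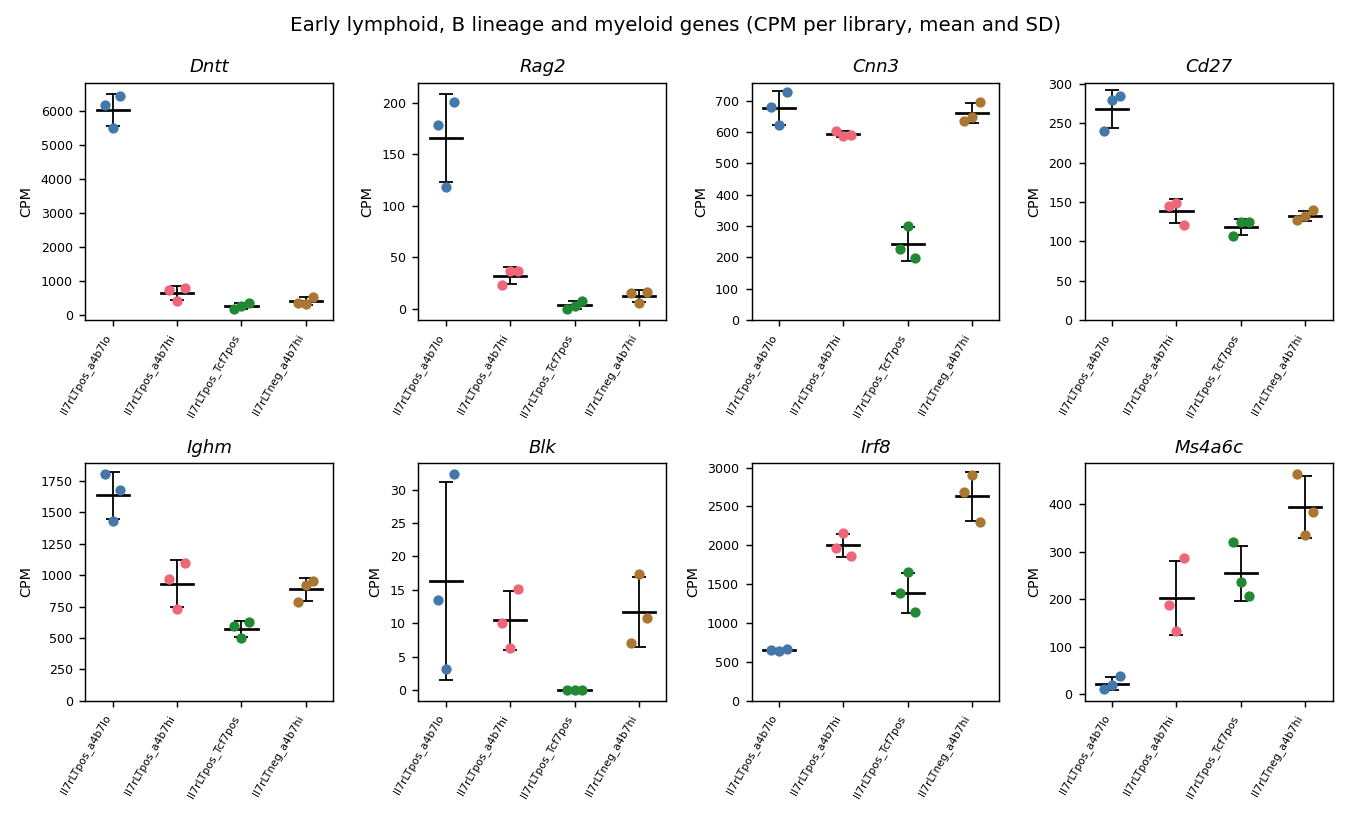
Expression in CPM (linear vertical axis) of early lymphoid, B lineage and myeloid genes in the 4 gates, with a point per library, the mean as a line and the SD as an error bar (n = 3). Dntt averaged 6050 CPM in Il7rLTpos_a4b7lo, and Cnn3 averaged 593 CPM in Il7rLTpos_a4b7hi and 242 CPM in Il7rLTpos_Tcf7pos.

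Of the genes called in the α4β7 step and in the Tcf7 step, 2 were the same by edgeR, Ctsb and Tmem229b, named because so few were shared and chosen after their values were seen. Both rose in the α4β7 step, by 0.74 and 1.02 on the log2 scale, and fell in the Tcf7 step, with log2 fold changes of -1.04 and -0.90. DESeq2 shared 78 genes between the steps, 17 in the same and 61 in opposite directions. Independent edgeR lists would share 0.19 genes higher and then lower. In 20 simulations of unchanged gates that shared the Il7rLTpos_a4b7hi libraries, 0 genes were called in either comparison, so their overlap of 0 could not have been otherwise and gives no chance level. These libraries enter both comparisons with opposite sign, and with 3 of them they could not be divided, so the overlap may come from the sharing in part or in full.

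Between YFP-positive and YFP-negative α4β7-high GFP-negative cells, which differ in the YFP mark of Il7r history, no gene was called by edgeR. Of 13672 tested genes, 845 had an unadjusted p under 0.05, a cut that unchanged genes pass at a share of 0.05 by chance. DESeq2 called 132 genes and limma voom 0, and the smallest edgeR adjusted p was 0.207. Of all tested genes 12.8% had no overlap between the gates, against the 10% of chance. Nfil3 was at 689 ± 136 CPM in Il7rLTpos_a4b7hi and 689 ± 56.7 CPM in Il7rLTneg_a4b7hi, Id2 at 150 ± 63.0 and 260 ± 119 CPM, and Tox at 135 ± 46.3 and 108 ± 40.4 CPM. Gata3 was at 37.3 ± 26.8 and 16.6 ± 9.68 CPM, and Il7r at 19.6 ± 18.4 and 8.73 ± 11.8 CPM. The YFP-negative libraries held 3.99, 0 and 22.2 CPM of Il7r and the YFP-positive ones 38.1, 1.29 and 19.3 CPM. Absence of YFP therefore need not mean absence of Il7r expression. The authors' deposited table for the same comparison likewise lists 0 of 10473 genes with an adjusted p under 0.05, with 693 (6.6%) at an unadjusted p under 0.05.

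Dendritic cell genes were the list called in this comparison, lower in Il7rLTpos_a4b7hi (camera adjusted p = 0.00196), with an adjusted p of 0.248 with an estimated correlation. It had an adjusted p of 0.13 without replicate 2 of Il7rLTpos_a4b7hi, in a range of 2e-05 to 0.25 over its alternatives. None of its 18 members was called over all genes by edgeR, with 5 at an unadjusted p under 0.05 and 1 called by DESeq2, and 2 fell adjusted over the list alone. Members of this list also moved in the other steps, where camera did not call it. Adjusted over the list alone, 6 rose and 2 fell in the α4β7 step (camera adjusted p = 0.0955). In the Tcf7 step 6 fell (camera adjusted p = 0.199). Cst3 (ENSMUSG00000027447), which encodes the protease inhibitor cystatin C, was at 554 ± 140 CPM in Il7rLTpos_a4b7hi and 1243 ± 339 CPM in Il7rLTneg_a4b7hi, and Runx2 at 84.0 ± 15.3 and 144 ± 39.6 CPM. Replicate 2 of Il7rLTneg_a4b7hi had 0 CPM of Xist and 46.4 CPM of the Y-linked Ddx3y, whereas replicate 2 of Il7rLTpos_a4b7hi had 44.4 and 0.773 CPM, so the libraries did not hold the same mix of sexes. Without replicate 1 or replicate 2 of Il7rLTneg_a4b7hi edgeR called 1 gene each, Dnajb2 and Tnni1, chosen after their values were seen.

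Across both steps, from the α4β7-low gate to the Tcf7 GFP-positive gate, 400 genes changed, 223 higher and 177 lower, among them the ILC transcription factor genes Nfil3 and Id2 and the lymphoid genes Dntt and Rag2. Nfil3 rose from 36.6 ± 8.80 to 678 ± 10.3 CPM (log2 fold change 4.21, SE 0.20, adjusted p = 1.5e-06) and Id2 from 10.4 ± 3.27 to 354 ± 165 CPM (adjusted p = 0.00039). Dntt fell from 6050 ± 478 to 251 ± 98.0 CPM (log2 fold change -4.59, SE 0.36, adjusted p = 6.7e-05) and Rag2, of the antigen receptor recombinase, from 166 ± 43.0 to 3.82 ± 4.09 CPM (adjusted p = 0.0088). Of the 400 genes, 399 had no overlap between the libraries of the gates, which a call nearly guarantees, so this is no separate evidence. Of all tested genes 20.3% had no overlap.

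Of the sort gate genes, Tcf7 rose from 0.570 ± 0.842 to 411 ± 35.3 CPM (adjusted p = 0.00083), Itgb7 to 869 ± 204 CPM (adjusted p = 5.6e-06) and Itga4 to 353 ± 42.7 CPM (adjusted p = 0.0011). Flt3 fell from 1197 ± 11.9 to 366 ± 119 CPM (adjusted p = 0.00079), and 3 sort gate genes rose and 2 fell adjusted over the list alone. Of 14 ILC transcription factors, 4 rose, 1 fell and 9 were not called, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.46e-07, adjusted p = 0.158 with an estimated correlation). Tox rose to 140 ± 27.9 CPM (adjusted p = 0.0021) and Gata3 to 46.2 ± 10.2 CPM (adjusted p = 0.018), while Ets1 fell to 5.89 ± 3.14 CPM (adjusted p = 0.00064). Zbtb16 had no count in the α4β7-low libraries and 15.5 ± 5.32 CPM in the GFP-positive ones (adjusted p = 0.07). Gata3 was not called without replicate 1, 2 or 3 of Il7rLTpos_a4b7lo or replicate 2 of Il7rLTpos_Tcf7pos (adjusted p = 0.054 to 0.075).

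Of 13 ILC precursor surface and signalling genes, 3 rose, 1 fell and 9 were not called, the same numbers as adjusted over the list alone. The list was higher by camera (adjusted p = 0.0312, adjusted p = 0.158 with an estimated correlation, adjusted p = 0.076 without Il7rLTpos_a4b7lo replicate 1). Cd7 rose to 37.9 ± 18.7 CPM (adjusted p = 0.0088) and Il2rb from 6.67 ± 7.67 to 114 ± 18.6 CPM (adjusted p = 0.038). Il17rb, a chain of the IL-25 receptor, rose from 7.93 ± 3.07 to 37.3 ± 8.34 CPM (adjusted p = 0.043). Il18rap, a chain of the IL-18 receptor, fell from 202 ± 38.8 to 60.2 ± 15.7 CPM (adjusted p = 0.0019). Of 9 NK lineage genes 1 rose, Il2rb, and 3 rose adjusted over the list alone (camera adjusted p = 0.0177, adjusted p = 0.158 with an estimated correlation). Its adjusted p was 0.095 without Il7rLTpos_a4b7lo replicate 1 and 0.075 without Il7rLTpos_Tcf7pos replicate 1, in a range of 0.016 to 0.16 over its alternatives. Il17rb was called in none of the 6 fits with 1 library left out (adjusted p = 0.063 to 0.16). Il2rb was called only without Il7rLTpos_a4b7lo replicate 2 (adjusted p = 0.062 to 0.14 in the others), and Cd7 in all but the fit without Il7rLTpos_a4b7lo replicate 2 (adjusted p = 0.05).

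Of 11 early lymphoid genes, 6 fell and 5 were not called, and 8 fell adjusted over the list alone (camera adjusted p = 4.52e-07, adjusted p = 0.158 with an estimated correlation). Cnn3 fell from 676 ± 53.3 to 242 ± 53.6 CPM (adjusted p = 0.00026) and Cd27 to 118 ± 9.78 CPM (adjusted p = 0.00061). Satb1 fell from 512 ± 55.1 to 232 ± 17.8 CPM (adjusted p = 0.019) and Notch1 from 145 ± 14.95 to 26.0 ± 13.1 CPM (adjusted p = 0.043). Of 12 B lineage genes, 2 fell, Ighm to 574 ± 64.7 CPM (adjusted p = 0.00038) and Blk at least 111-fold (adjusted p = 0.0024), and 4 fell adjusted over the list alone (camera adjusted p = 0.000427, adjusted p = 0.158 with an estimated correlation). Of 18 dendritic cell genes, 2 fell and 16 were not called, but 5 rose and 5 fell adjusted over the list alone, and the list was not called by camera (adjusted p = 0.598). Of its members, Tcf4, an E protein gene, fell from 194 ± 15.05 to 62.9 ± 21.0 CPM (adjusted p = 0.0017) and Cox6a2 from 172 ± 43.9 to 15.6 ± 2.42 CPM (adjusted p = 0.00064). Of 15 stem cell and multipotent progenitor genes 1 fell, and 3 fell adjusted over the list alone. Meis1 of that list fell from 98.0 ± 32.9 to 30.7 ± 7.48 CPM (adjusted p = 0.042). Of the 6 fits with 1 library left out, none called Notch1 (adjusted p = 0.057 to 0.13), and Satb1 and Meis1 were called only without Il7rLTpos_a4b7lo replicate 3 (adjusted p = 0.051 to 0.08 and 0.077 to 0.16 in the others).

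Of 17 myeloid and granulocyte-monocyte genes, 4 rose and 13 were not called, and 7 rose adjusted over the list alone (camera adjusted p = 1.12e-05, adjusted p = 0.283 with an estimated correlation). Ms4a6c rose to 255 ± 58.8 CPM (adjusted p = 0.00079) and Irf8 to 1391 ± 257 CPM (adjusted p = 0.00079). Ly86 rose to 240 ± 44.5 CPM (adjusted p = 0.006) and Cebpa from 6.49 ± 0.794 to 28.3 ± 1.38 CPM (adjusted p = 0.027). Of 9 mast cell and basophil genes 2 rose, as also adjusted over the list alone, and the list was not called by camera (adjusted p = 0.0812). Cpa3, a mast cell protease gene, rose from 3.86 ± 6.60 to 567 ± 57.7 CPM (adjusted p = 0.034) and Srgn from 567 ± 131 to 914 ± 77.3 CPM (adjusted p = 0.03). S100a8, a neutrophil gene, was at 203 CPM in replicate 3 of Il7rLTpos_Tcf7pos against 1.61 and 1.43 CPM in replicates 1 and 2. With 1 library left out, Cebpa was called in none of the 6 fits (adjusted p = 0.059 to 0.11). Cpa3 was called only without Il7rLTpos_a4b7lo replicate 3 (adjusted p = 0.052 to 0.092 in the others), and Srgn only without Il7rLTpos_a4b7lo replicate 3 or Il7rLTpos_Tcf7pos replicate 2 (adjusted p = 0.079 to 0.12 in the others). None of 13 interferon response genes was called over all genes by edgeR, with 7 at an unadjusted p under 0.05 and 5 called by DESeq2, and 6 fell adjusted over the list alone. Oas1a was at 90.6 ± 33.7 CPM in the α4β7-low and 28.1 ± 4.66 CPM in the GFP-positive gate. The list was lower by camera (adjusted p = 0.00129), with an adjusted p of 0.532 with an estimated correlation.

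Among the remaining genes with the largest changes between these gates, Plbd1 and Cldn15 were at 0 in the α4β7-low libraries and at least 138-fold and 82-fold higher in the GFP-positive ones (adjusted p = 0.038 and 0.047). Lrp1 and Apcdd1 were at 0 in the GFP-positive libraries and at least 227-fold and 216-fold lower (adjusted p = 0.00034 and 0.0099). The count of 400 was 234 and 230 without replicates 1 and 2 of Il7rLTpos_a4b7lo, 259 without replicate 1 of Il7rLTpos_Tcf7pos, and 222 in a fit of only these gates. It was 1094 with DESeq2 (535 higher and 559 lower), 625 with limma voom (267 higher and 358 lower), so that the larger direction was not the same between tools, and 211 with the libraries numbered 3 left out. Plbd1 and Cldn15 were called in none of the 6 fits with 1 library left out (adjusted p = 0.066 to 0.12 and 0.082 to 0.14).

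Of the 17 gene lists tested, 7 were called by camera in no comparison. Their smallest camera adjusted p over the 4 comparisons was 0.0731 for cell division, 0.0873 for Notch targets, 0.107 for stem cell and multipotent progenitor genes, and 0.164 for DNA replication. It was 0.284 for E protein and Id genes, 0.576 for immediate early genes and 0.762 for T lineage genes. In the eosinophil list 2 genes were measured, too few for a test, and neither was called by edgeR or DESeq2 in any of the 4 comparisons, with 1 at an unadjusted p under 0.05 in each of the α4β7 and Tcf7 steps. Prg2 was at 453 CPM in replicate 3 of Il7rLTpos_a4b7hi against 0.694 and 1.38 CPM in replicates 1 and 2. No sex-linked gene of 5 was called by edgeR or DESeq2 in any of the 4 comparisons, with 1 at an unadjusted p under 0.05 between the gates that differ in the YFP mark of Il7r history.

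**Figure D3:**
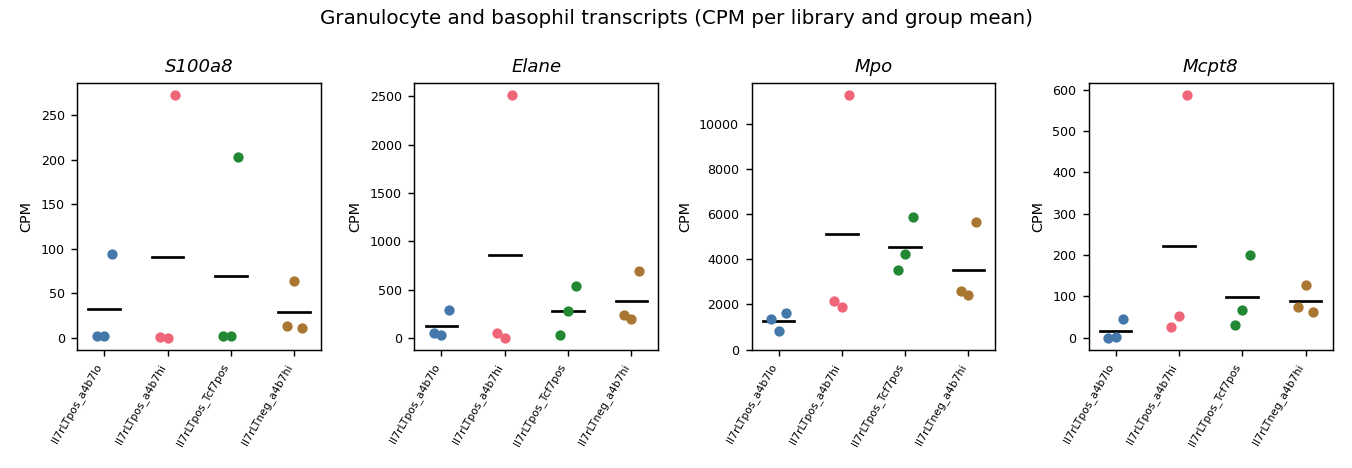
Expression in CPM (linear vertical axis) of granulocyte and basophil transcripts in the 4 gates, with a point per library and the mean as a line. Replicate 3 of Il7rLTpos_a4b7hi had the highest value of each gene, 273 CPM of S100a8, 2514 CPM of Elane, 11277 CPM of Mpo and 587 CPM of Mcpt8.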

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

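Leaving out the libraries numbered 3 was chosen only after the data were seen. The α4β7 step gave 237 called genes, the Tcf7 step 14, the Il7r history 0 and the comparison across both steps 400. RLE factors, no filter and a filter of 5 CPM kept these counts within 1.5 times. DESeq2 gave 679, 313, 132 and 1094, and limma voom moved the Tcf7 step to 8 and the comparison across both steps to 625. It called 199 genes higher and 139 lower in the α4β7 step, against 186 and 51, and 267 and 358 across both steps, against 223 and 177. Fits of only the groups compared gave 149, 0, 0 and 222, with fewer samples to estimate the spread. Without the libraries numbered 3 the counts were 74, 0, 0 and 211, with fewer samples in each group. Leaving out 1 library at a time gave 136 to 192, 8 to 26, 0 to 1 and 230 to 331. The cause of the differences between tools was not tested. The genes shared by the α4β7 and Tcf7 steps went from 2 to 78 with DESeq2, 61 of them in opposite directions; the cause was not tested.

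Of 68 list tests 17 were called, 0 with an estimated correlation, 19 without the libraries numbered 3, and 11 to 22 with 1 library left out. Of the 81 called values of named genes, none changed direction under RLE factors, DESeq2, the libraries numbered 3 left out or any single library left out. Nearly all called genes had no overlap between the gates, which leaves almost no room for a change of direction. The kept direction is therefore no separate evidence. With single libraries left out, 116 of 486 values were no longer called, and 55 of the 81 stayed called in each such fit. Without the libraries numbered 3, 42 of the 81 were no longer called and 39 stayed called, with DESeq2 1 was no longer called and with RLE factors 0.

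The replicate numbers were not taken to pair the samples. Of 18 same-numbered pairs from different gates 2 had a correlation of deviations over 0.1, with a range of -0.01 to 0.16. The median was 0.04, against -0.02 for other pairs. In 29 of 36 cases a library correlated best with its own number in another gate, where chance would pick 1 of 3 numbers. This is a hint of pairing from the data that the main test, without a block, does not use. With the replicate number as a block the counts were 252, 8, 0 and 412, the list calls 19 and the shared genes 1. Of the 81 called values of named genes 9 were no longer called with the block. None changed direction, which the lack of overlap between gates nearly guarantees.

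Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. The other splits mix both gates in each group, which widens the spread where the gates differ, so few edgeR calls are likely there. In the α4β7 step the real split called 237 genes and the highest other split 0, and 1 of 10 splits gave as many. In the Tcf7 step these were 14 and 0, with 1 of 10, and across both steps 400 and 0, with 1 of 10. By Il7r history they were 0 and 1, and 10 of 10 gave as many, which a real count of 0 makes certain. Depth was 16937905 to 26758916 counts, and changes of 2-fold were mostly missed in simulated data.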

Other observations

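The description of positions in the first paragraph and the test of the myeloid list were chosen only after their results, or values close to them, had been seen. Genes that rose between the α4β7-low and the Tcf7 GFP-positive gates sat closer to the latter in the α4β7-high GFP-negative gate than genes that fell did. On the scale of log2(CPM + 0.5), the 223 higher genes sat at a median of 87.2% of the way in Il7rLTpos_a4b7hi (quartiles 69.9 and 104) and the 177 lower genes at 54.8% (quartiles 35.3 and 76.8). The 3 libraries had medians of 87.5%, 89.2% and 89.5% for the higher genes and 52.2%, 58.8% and 49.8% for the lower ones. In Il7rLTneg_a4b7hi the medians were 96.3% and 61.6%. The α4β7-high GFP-negative libraries took no part in ranking these genes by fold, but they shared the estimate of spread, and the difference between higher and lower genes was not tested. Choosing genes by a large difference between the end gates exaggerates that difference.

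Mature neutrophil, basophil and red cell transcripts were mostly higher in replicate 3 of Il7rLTpos_a4b7hi than in its replicates 1 and 2, a pattern that the other libraries numbered 3 shared in part. Carry-over of mature marrow cells or their RNA is a candidate source. Of 10 mature neutrophil markers outside the fixed lists, listed before their values were seen, all 10 were higher in this library than in the mean of replicates 1 and 2, with a median log2 ratio of 6.76, and S100a8 was at 273 CPM against 0.446 and 0 CPM. The ratio was 5 in Il7rLTpos_a4b7lo and 6.47 in Il7rLTpos_Tcf7pos but -1.24 in Il7rLTneg_a4b7hi, where S100a8 was highest in replicate 2. For 9 mast cell and basophil genes the median log2 ratio was 3.86 in Il7rLTpos_a4b7hi, 2.91 in Il7rLTpos_a4b7lo, 2.85 in Il7rLTpos_Tcf7pos and -0.68 in Il7rLTneg_a4b7hi. For 12 erythroid and megakaryocyte genes it was 2.52, 0.03, 1.54 and 1.16 in the same order. The lineage gate should remove mature neutrophils, so cells, free RNA and mixing between libraries stay open, as does a difference between animals, and no biological explanation was tested.

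The values argue against that background as the whole source of the rise of the myeloid list in the α4β7 step. With the libraries numbered 3 left out the list kept a camera adjusted p of 7.4e-05 in the same direction, against a range of 1e-09 to 0.22 over its alternatives. Irf8 was at 1967, 2163 and 1867 CPM and Ly86 at 288, 251 and 246 CPM in the 3 libraries of Il7rLTpos_a4b7hi, above all α4β7-low libraries. The background may still set the levels of Mpo and Elane in replicate 3, and the list was not called with an estimated correlation.

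Tcf7 was at 160 CPM in replicate 2 of the GFP-negative Il7rLTpos_a4b7hi, 31.7% of the way from Il7rLTneg_a4b7hi to Il7rLTpos_Tcf7pos, and GFP-positive cells carried into that gate may be a source. Over 23 other genes higher in Il7rLTpos_Tcf7pos, chosen without the Il7rLTpos_a4b7hi libraries, replicate 2 sat at a median of 61.0% (95% bootstrap interval 41.4 to 79.0). This met the criterion set beforehand for carry-over, a share of at least that of Tcf7. Carry-over alone would give about the share of Tcf7, and the interval lies above 31.7%, so the criterion was too loose. The bootstrap resampled genes within 1 library and does not measure the spread between libraries. The test separates little, because replicates 1 and 3 sat at 25.2% and 30.9% of the way with Tcf7 shares of -0.2% and -5.3%. Perp, among the 23 genes, and Tox2, not among them, were singled out after their values were seen. They averaged 51.1 and 16.8 CPM in Il7rLTpos_Tcf7pos and were at 0 CPM in replicate 2, below what such a share would bring. Perp was also at 0 CPM in replicate 1. Others of the 23 went the other way in replicate 2, such as Gata3 and Cttn at 67.9 and 102 CPM. Their means in Il7rLTpos_Tcf7pos were 46.2 and 66.8 CPM, so single genes decide nothing here. Cells that make Tcf7 transcripts before GFP can be detected would give the same median and stay open.

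DESeq2 called 132 genes by Il7r history where edgeR called 0, and chance dropout between low-input libraries is a candidate explanation. The 9 other splits of the 6 libraries gave 51 to 87 DESeq2 calls, and 0 of them as many as the real split. The criterion set beforehand took this as evidence against chance dropout, which was wrong by design, since 10 splits cannot give a share under 0.05. Of the 132 genes, 65.2% had a library at 0 counts against 22.4% of all tested genes. Chance dropout and a difference by Il7r history cannot be told apart for these genes, because the splits are too few.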
